A study of Mus musculus with 30 samples.

How the data were processed

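Hippocampal RNA of 30 male NMRI mice, 15 resistant and 15 responsive to phenytoin, was measured on single-colour Illumina bead arrays, 1 array per mouse. Per the labels' protocols, whole hippocampi were snap frozen, total RNA was purified on RNeasy Plus columns, and biotinylated cRNA was made with the Illumina TotalPrep kit. The submitters' processing notes name the R package lumi, with no version, and the steps it was used for are not given in the sources used here.

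The authors deposited a table that is named as not normalised, with a log2 signal and a detection p-value for each of 25697 probes and each array. Its values were checked before use. Of the 497674 signals below 200 on the linear scale, 99.9% were whole multiples of 0.0001 (within 0.05 of that step), so the deposited log2 values are plain logarithms of scanner signals and not variance-stabilised ones. The deposited detection p-values move in steps of 1 in 798, the size of the negative control set they were computed from. The authors also deposited processed log2 values. On every array these ranked the probes as the unprocessed values did (lowest Spearman correlation 1), and at each rank the arrays differed by at most 0.0016. Quantile normalisation of the unprocessed log2 signals reproduced them to within 6e-09, so no background correction was applied between these tables. Their median was 7.21 in every column. Array medians before normalisation ran from 7.06 to 7.38 (log2).

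Here the log2 signals were returned to the linear scale and corrected and normalised with neqc in limma 3.58.1 (R 4.3.3). It fits a normal and exponential mixture whose background is inferred from the detection p-values, adds an offset of 16, quantile-normalises the arrays and takes log2. A probe was kept when its detection p was under 0.05 on at least 15 of the 30 arrays, which left 12588 probes. Gene names came from the platform annotation. It named 1 gene for 23978 probes, several for 0 and none for 1719, and 705 of the kept probes had no name. Entrez identifiers of 23962 probes matched the RefSeq gene table of mouse assembly GRCm38.p6, and 0 symbols had to be updated. That table was otherwise used only to match list genes through older symbols and to tell which genes neighbour each other.

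Resistant mice were compared with responders by lmFit and eBayes with an intensity trend on all 30 arrays, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over the kept probes. Differences are log2, resistant minus responder. Before the data were examined, 38 gene lists were fixed, 21 of pathways and 17 of cell type or region markers. Each list was tested with camera at its preset inter-gene correlation of 0.01, with 1 probe per gene, the kept probe of highest mean, and at least 5 measured genes. All 38 lists qualified, and 8 list genes were matched through an older symbol. Camera with an estimated correlation and fry were run beside it. List means per mouse were compared by two-sided permutation tests of 100000 resamples. For 8 lists the median, the mean and the test differ in sign. These are extracellular matrix and perineuronal net, neocortex, reactive astrocyte genes, GABA receptors, striatum, microglia, neuropeptides, and potassium and HCN channels.

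The genes named follow a rule fixed before the data were examined, apart from those declared as named after their values were seen. It takes the probes past an adjusted p of 0.05 and, since fewer than 10 passed, the 10 probes with the smallest p in each direction. To these it adds up to 4 members of each list described, with the smallest p, and 12 genes named whatever their values (Scn1a, Scn2a, Scn3a, Scn8a, Abcb1a, Abcb1b, Abcc1, Abcg2, Ephx1, Gfap, Fos and Ttr). A gene with several probes is represented by its brightest kept probe unless another probe is named. No gene had probes of opposite sign that were both past an unadjusted p of 0.05 among those named.

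The fit was tested on simulated data, made by adding known changes to 200 probes per draw of the array residuals with mice assigned to groups at random (10 draws, 12588 probes). Changes of 0.2, 0.4 and 0.8 on the log2 scale were recovered for 32.2%, 77.2% and 98.6% of the changed probes. With 200 changed probes the adjusted threshold is looser than in the real comparison, where 1 probe passed. These shares may therefore overstate the recovery there. A median of 4.5 unchanged probes per draw was also called, at most 11. With no change added, the highest number of probes called in a draw was 0. The median half-width of a probe's 95% interval in the real comparison was 0.15, and the number of arrays limits this precision.

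The alternatives tried were no background correction, median scaling, the authors' processed values, no filter, a stricter filter (detection p under 0.01 on all arrays, 9423 probes), array weights, a robust prior, and the replicate number as a block. Further alternatives were covariates for choroid plexus, for neighbouring brain regions and for the first residual component, and each mouse left out in turn. Alternatives chosen after the data had been seen were the sample number in 2 parts (1 to 16 and 17 to 30) as a block or alone, and runs of 8 consecutive numbers as a block. No chip barcode was given for the arrays in the tables used here, so the chip could not enter the model. Arrays within a group were compared for duplicates, and the highest correlation of their deviations from the group means was 0.378.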

Results

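Gene expression was measured in the hippocampus of 30 male NMRI mice, an outbred stock, at 12 weeks of age. Each mouse had been tested for its response to phenytoin, a blocker of voltage-gated sodium channels used against seizures, in the 6 Hz model, in which brief electrical stimulation through the cornea evokes psychomotor seizures. The resistant group held 15 mice that did not respond to the drug, and the responder group held 15 mice that did. Each hippocampal RNA sample was hybridised to 1 bead array of 25697 probes. Between 12330 and 13223 probes per array were detected above the negative controls. The number detected averaged 12811 ± 241 (SD, n = 15) in resistant and 12873 ± 245 (SD, n = 15) in responder mice, a difference within the spread between mice (two-sided permutation test, 100000 resamples, p = 0.492). Detection on at least 15 arrays kept 12588 probes, which name 8841 genes. The number of arrays limits the precision, and the log2 difference of the median probe had an SE of 0.07.

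The comparison of resistant with responder mice asks whether the hippocampus differs in expression between mice that the drug protects and mice that it does not. The groups are defined by the outcome of a seizure test, so effects of seizures in that test cannot be told apart from resistance. Differences were small. The probe with the strongest evidence was one for Eif5a, a translation factor that carries the amino acid hypusine, at a level 0.86 times that of responders. Next came Rbm3, an RNA-binding protein induced by mild cold, at 0.74 times the responder level. Cirbp, another cold-induced RNA-binding protein, lay at 0.82 times the responder level. Per2, a repressor in the circadian clock, lay 1.28-fold higher on one probe and Mul1, a ubiquitin ligase of the outer mitochondrial membrane, 1.97-fold higher in resistant mice. Of these probes, that of Eif5a alone passed the 5% false discovery threshold.

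The Eif5a probe (ILMN_2678828) read 10.29 ± 0.12 in resistant and 10.51 ± 0.08 in responder mice (normalised log2 signal, mean ± SD, n = 15 each). The log2 difference was -0.22 (SE 0.04, limma adjusted p = 0.0395), and 0 of 15 resistant mice exceeded the responder median. The other, brighter Eif5a probe (ILMN_2686044) read 10.82 in both groups, with a log2 difference of 0.0021 (limma adjusted p = 0.995), so the gene's probes disagree and the difference belongs to one probe. It passed with 15 of the 30 mice left out in turn and did not with the other 15. The log2 difference stayed at -0.22 (SE 0.04) with the choroid plexus markers as a covariate (adjusted p = 0.0756) and with no filter on dim probes, where more probes are adjusted for (adjusted p = 0.0759). With median scaling it was -0.18 (SE 0.05, adjusted p = 0.263). Counting these, the probe did not pass in 6 of 15 alternative settings.

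None of the probes named next passed the threshold. Together with the Eif5a probe they are the 10 with the smallest p in each direction. Among those lower in resistant mice, Rbm3 read 9.10 ± 0.24 against 9.54 ± 0.26 (SD, n = 15 each), a log2 difference of -0.44 (SE 0.09, limma adjusted p = 0.0888). Cirbp read 8.61 ± 0.17 against 8.89 ± 0.19, a log2 difference of -0.28 (SE 0.06, limma adjusted p = 0.178). For each of these genes, 1 of 15 resistant mice exceeded the responder median. Sqstm1, the autophagy receptor p62, differed by -0.16 (SE 0.03, limma adjusted p = 0.125). The remaining probes of this direction had adjusted p of 0.31 each. They were those for Akr1a1, an aldehyde reductase, at -0.10, Sumo3, a small ubiquitin-like modifier, at -0.25, Gde1, a glycerophosphodiesterase, at -0.17, and Vldlr, a receptor for reelin, at -0.22. The brightest probes of Akr1a1, Gde1 and Vldlr lay at -0.06 (p = 0.0353), -0.04 (p = 0.23) and -0.17 (p = 0.00303), and the Sumo3 probe is its brightest. A probe for Pink1, the kinase that marks damaged mitochondria, lay at -0.22, while the brighter Pink1 probe lay at 0.07 (p = 0.172). The unnamed probe ILMN_2713686 lay at -0.25.

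Among probes higher in resistant mice, Srrt, which links the nuclear cap-binding complex to RNA processing, read 9.50 ± 0.07 against 9.31 ± 0.13 (SD, n = 15 each). Its log2 difference was 0.19 (SE 0.04, limma adjusted p = 0.125), and its other kept probes lay at 0.12 and 0.13. Dusp4, a phosphatase that inactivates MAP kinases, differed by 0.37 (SE 0.08, limma adjusted p = 0.125), and its dimmer kept probe by 0.08. All 15 resistant mice exceeded the responder median for Srrt and for Dusp4. Mul1 read 7.86 ± 0.71 against 6.89 ± 0.56, a log2 difference of 0.98 (SE 0.22, limma adjusted p = 0.163). Its values fell into separate levels, with no mouse between 7.00 and 7.96. Above that gap lay 11 resistant and 2 responder mice. Scd1, a fatty acid desaturase, differed by 0.26 (SE 0.06, limma adjusted p = 0.178). Per2 differed by 0.35 on one probe (limma adjusted p = 0.263) and by 0.27 on its brightest probe (limma adjusted p = 0.376). The remaining probes, with adjusted p of 0.31, named E4f1 (0.34), Lman2l (0.26), Rbm45 (0.57), Dnajb5, a co-chaperone (0.36), and Acot8 (0.38). Lman2l had a further probe at 0.33. The brightest Acot8 probe, by contrast, lay at 0.02.

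**Figure D1:**
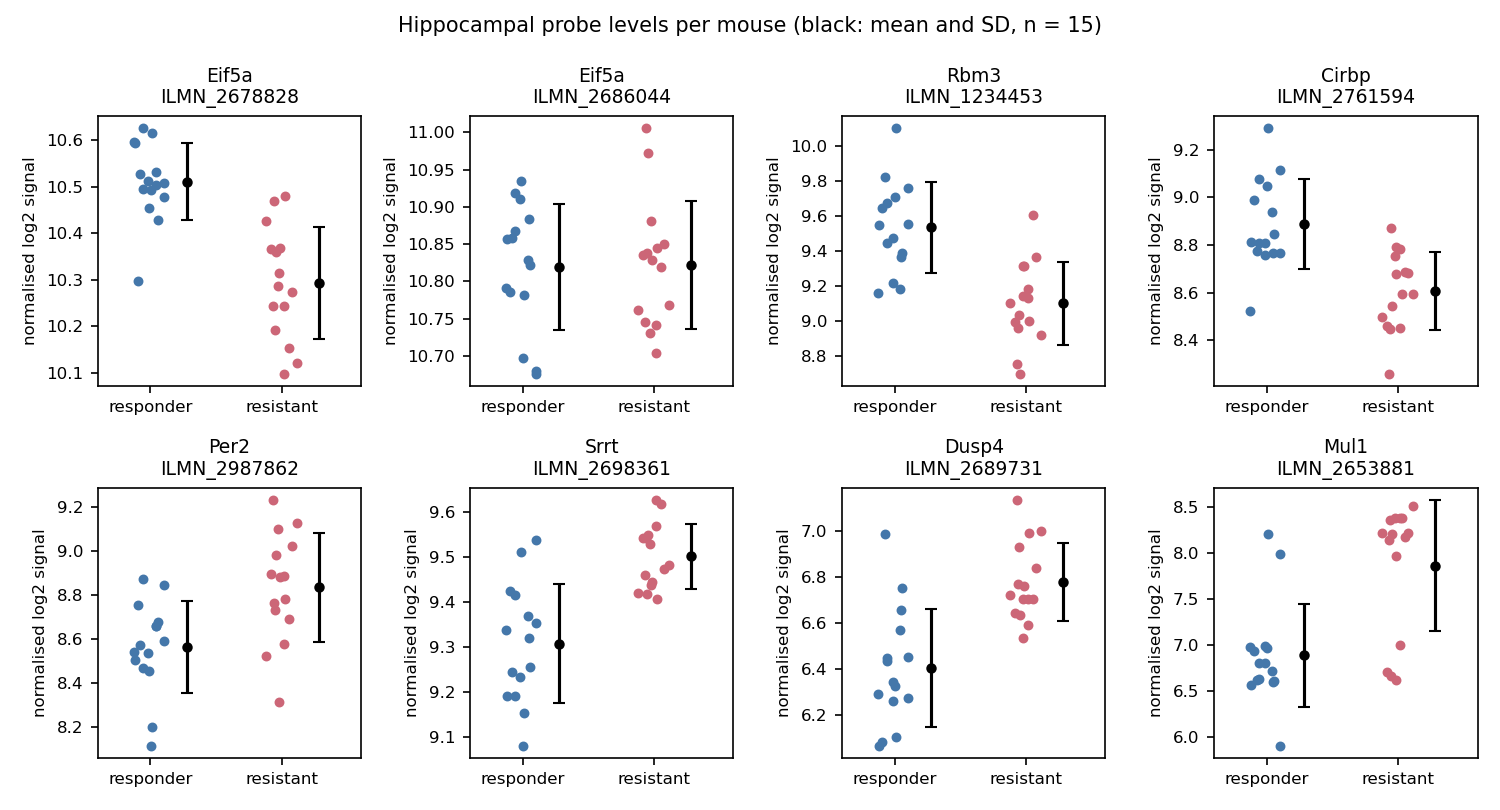
Normalised log2 signal of 8 probes (vertical axes, each with its own range) in responder and resistant mice. Each point is 1 mouse, and black marks give the mean and SD of 15 mice. The Eif5a probe at the top left lies lower in resistant mice (10.29 against 10.51), the other Eif5a probe does not, and Mul1 shows separate high and low levels in both groups.

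Genes of the drug's target and handling were set down before the data were examined. Of the voltage-gated sodium channel list, 5 of 15 genes were measured, and 0 had an unadjusted p under 0.05 (camera p = 0.301, direction up). Scn1a read 8.38 ± 0.49 in resistant and 8.43 ± 0.53 in responder mice (SD, n = 15 each), a log2 difference of -0.05 with a 95% interval from -0.40 to 0.30. Scn8a differed by -0.04, with an interval from -0.29 to 0.20. Both differences changed sign in some of the alternative settings. The auxiliary subunits Scn3b and Scn2b lay at 0.20 (p = 0.0576) and 0.08 (p = 0.293). No probe named Scn2a or Scn3a. Probes for the efflux pumps Abcb1a, Abcb1b, Abcc1 and Abcg2 were detected on 0 of 30 arrays each, so these genes were not tested. Of the 6 measured genes of drug efflux and uptake, 1 was lower at unadjusted p under 0.05, the carnitine transporter Slc22a5 at -0.18 (camera p = 0.206 for the list), and Abcc5 lay at 0.10 (p = 0.226).

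Of 13 measured genes of drug metabolism and xenobiotic receptors, 3 were lower and 0 higher at unadjusted p under 0.05 (camera p = 0.156, direction down). Ephx1, the microsomal epoxide hydrolase, read 8.87 ± 0.32 against 9.18 ± 0.49, a log2 difference of -0.31 with a 95% interval from -0.60 to -0.03 (limma adjusted p = 0.636). Only 2 of 15 resistant mice exceeded its responder median. The Ephx1 signal also differed with the choroid plexus markers described below. In the responder mouse with the highest mean of those markers (10.6) it read 9.76, and in that with the lowest (5.77) 8.20. The same comparison in resistant mice gave 9.21 (mean 9.86) against 8.38 (mean 5.31), so part of the Ephx1 difference may follow these markers. Nat1 lay at -0.22 (p = 0.0195) and Gstm1 at -0.12 (p = 0.0256). Of 20 measured known epilepsy genes, 0 passed an unadjusted p of 0.05 (camera p = 0.2). The nearest were Dnm1 at -0.15 (p = 0.0842) and Kcnq3 at 0.20 (p = 0.0892).

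Of the 38 gene lists, 2 passed the 5% threshold with camera at its preset correlation of 0.01. All 12 measured choroid plexus markers lay lower in resistant mice, by a median log2 difference of -0.86 (camera adjusted p = 0.000147), although 0 of them had an unadjusted p under 0.05. The markers vary together, and with an estimated correlation the list had an adjusted p = 0.951. The mean of the markers read 7.74 ± 1.49 in resistant and 8.59 ± 1.90 in responder mice (SD, n = 15 each; two-sided permutation test, 100000 resamples, p = 0.181). Their examples were Calml4 at -0.87, the water channel Aqp1 at -1.07, the tight-junction protein Cldn2 at -0.91 and Kl at -0.73. Ttr, which carries thyroid hormone, differed by -0.26 (95% interval -1.69 to 1.17). It lay between 14.28 and 14.69 in 19 of the 30 mice, while the mean of the other markers ran from 7.14 to 10.2 in them, so its signal was near a ceiling that compresses the difference. The first principal component, 17.2% of the variance, followed the choroid plexus mean over the 30 mice. Pearson's r had a size of 0.982 (permutation p = 1e-05, the smallest that 100000 permutations can give) and Spearman's rho of 0.977 (permutation p = 1e-05). Without the 2 mice farthest from the median, r had a size of 0.978. The adjusted p over the 5 components examined was 5e-05. The markers were among the probes from which the component was computed, so the relation is not between independent measures.

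Oligodendrocyte markers lay higher in resistant mice, 14 of 16 measured genes, by a median log2 difference of 0.14 (camera adjusted p = 0.0318). With an estimated correlation the adjusted p was 0.951. The mean of the markers read 9.61 ± 0.21 against 9.49 ± 0.26 (two-sided permutation test, 100000 resamples, p = 0.185). Ugt8a, which makes the galactolipid of myelin, lay at 0.38 (SE 0.10) and was the 1 gene past the threshold adjusted over the list alone (0.0115), but not over all probes (limma adjusted p = 0.31). Fa2h lay at 0.19 and Cldn11 at 0.17. Markers of oligodendrocyte precursors had 0 of 7 measured genes past an unadjusted p of 0.05 (camera p = 0.669).

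**Figure D2:**
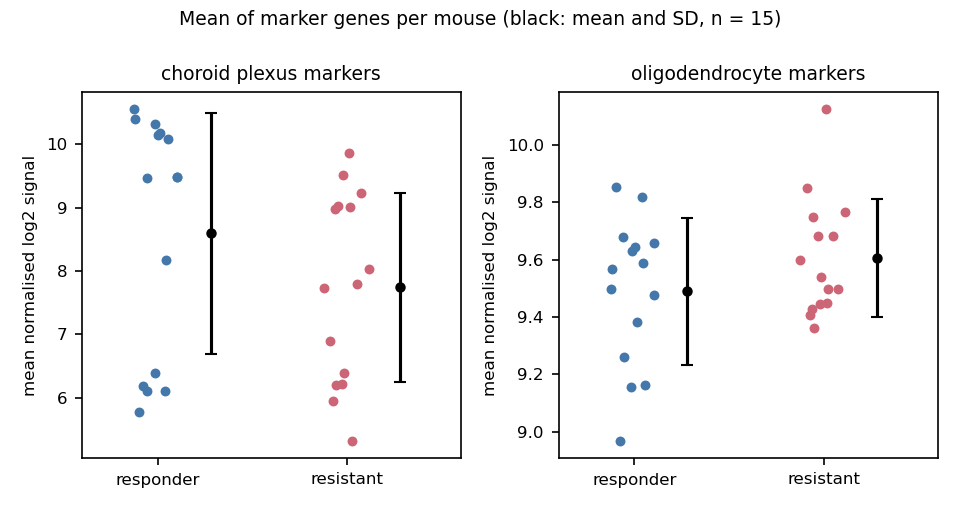
Mean normalised log2 signal of 12 choroid plexus markers and 16 oligodendrocyte markers (vertical axes) per mouse in responder and resistant groups. Each point is 1 mouse, and black marks give the mean and SD of 15 mice. High and low choroid plexus levels occur in both groups.

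The other lists did not pass. Of 7 adenosine signalling genes, 6 lay lower, with 1 at unadjusted p under 0.05 (camera adjusted p = 0.0691). These included the purine nucleoside phosphorylase Pnp at -0.18 (p = 0.0121) and the transporter Slc29a4 at -0.21 (p = 0.12). Of 10 ependymal markers, 9 lay lower (camera adjusted p = 0.0691), with Tekt1, a protein of cilia, at -0.53 (p = 0.0285). Foxj1, the regulator of cilium formation, went the other way at 0.24 (p = 0.0804). With an estimated correlation, 0.687 for the ependymal list, its camera p was 0.304 (adjusted p = 0.951). For the adenosine list the estimated correlation was 0.0285 and the camera p was 0.0159 (adjusted p = 0.604). Interferon-stimulated genes were lower in 11 of 16 (camera adjusted p = 0.115), with H2-D1 at -0.38 (p = 0.0109) and Irf1 at -0.15 (p = 0.0295). Inflammatory genes were lower in 7 of 11 (camera adjusted p = 0.297), with Nfkbia at -0.22 (p = 0.017) and Icam1 at -0.28 (p = 0.045). Between the same groups the mean of the choroid plexus markers differed by -0.85.

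Of 16 circadian clock genes, 3 were higher and 1 lower at unadjusted p under 0.05 (camera p = 0.0927, direction up). Per2 passed when adjusted over the list alone (0.0288). Per1 lay at 0.18 (p = 0.0435), Nfil3 at 0.13 (p = 0.0486) and Rorb at -0.21 (p = 0.0481). Of 25 immediate early genes, 3 were higher and 3 lower at unadjusted p under 0.05 (camera p = 0.278). Klf2 and Junb lay at -0.31 each, and Nptx2 at 0.23 and Bdnf at 0.16. Fos read 9.64 ± 0.39 against 9.90 ± 0.60 (SD, n = 15 each), a log2 difference of -0.26 with a 95% interval from -0.60 to 0.09.

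Synaptic gene lists had few members past an unadjusted p of 0.05. The count was 0 of 19 for glutamate receptors and transporters (camera p = 0.985), 0 of 14 for GABA receptors and the inhibitory synapse (camera p = 0.712) and 0 of 19 for vesicle release (camera p = 0.085). It was 0 of 29 for potassium and HCN channels (camera p = 0.96) and 0 of 14 for calcium channels (camera p = 0.649). The members with the smallest p included Grm7 at 0.14 and Glul, glutamine synthetase, at 0.22. Abat, which degrades GABA, lay at 0.08, Gad1, which makes it, at 0.08, and Kcnip4 at 0.18. Of the vesicle release genes, Rab3a lay at -0.06, Rims2 at -0.11, Cplx2 at -0.23 and Sypl at 0.09. Reactive astrocyte genes had 1 of 16 lower (camera p = 0.465), the endotoxin co-receptor Cd14 at -0.33 (p = 0.0316). Gfap, the astrocyte filament protein, read 8.91 ± 0.17 against 9.04 ± 0.25, a log2 difference of -0.13 with a 95% interval from -0.28 to 0.02.

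**Figure D3:**
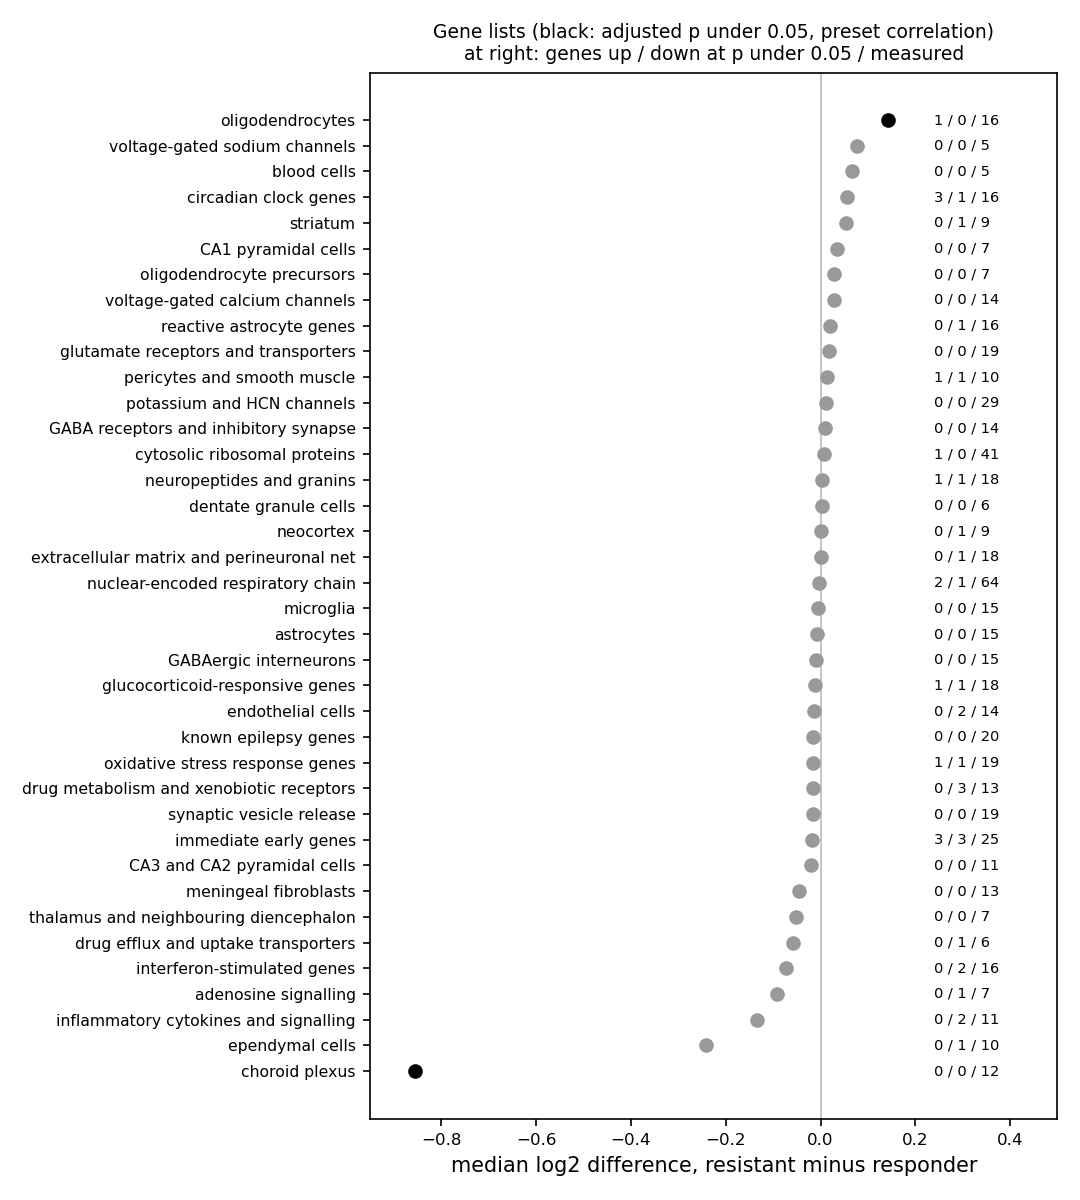
Median log2 difference, resistant minus responder (horizontal axis), of the measured genes of 38 lists, 1 point per list. Black points passed an adjusted p of 0.05 with camera's preset correlation, and the figures at the right count the genes higher and lower at unadjusted p under 0.05 and the genes measured. Choroid plexus (-0.86) and oligodendrocytes (0.14) lie at the ends, and neither passed with an estimated correlation (adjusted p = 0.951 each).

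Across all 12588 probes, 1 passed the 5% threshold, lower in resistant mice, and 2 had an adjusted p under 0.1. At unadjusted p under 0.05 there were 951, of which 535 were higher and 416 lower, beside 629.4 that 5% of the probes would give. With median scaling in place of quantile normalisation, 924 were higher and 229 lower. A log2 difference of over 0.5 in size was seen for 57 probes and of over 1 for 4. The third principal component, 7.31% of the variance, followed the sample number, which alternates between the groups. Pearson's r had a size of 0.622 (permutation p = 0.00031, adjusted p over the 5 components = 0.00155) and Spearman's rho of 0.64 (permutation p = 0.00022). Without the 2 samples at the ends of the numbering, r had a size of 0.614. The fourth component, 4.73% of the variance, also followed the sample number, with sizes of 0.5 for r (permutation p = 0.00444, adjusted p = 0.0111) and 0.412 for rho (permutation p = 0.025), and of 0.393 for r without those 2 samples. Within sample numbers 1 to 16 the log2 difference was -0.15 for the Eif5a probe, -0.54 for Rbm3, -0.32 for Cirbp, 0.69 for Mul1 and 0.22 for the Per2 probe of smallest p. Within numbers 17 to 30 it was -0.30 for Eif5a, -0.32 for Rbm3, -0.24 for Cirbp, 1.30 for Mul1 (limma adjusted p = 0.0452) and 0.51 for Per2 (limma adjusted p = 0.0324). None of the other values passed within its part, with limma adjusted p from 0.0768 (Eif5a, 17 to 30) to 0.821 (Per2, 1 to 16). The parts were chosen after the data had been seen, and the genes were picked over the same mice.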

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

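The settings that use the sample number were chosen after the data had been seen, and the others before. The number of probes past the 5% threshold, 1 in the main setting, was 0 with no filter, with the choroid plexus covariate and within sample numbers 1 to 16. It was 2 with the parts 1 to 16 and 17 to 30 or the runs of 8 sample numbers as a block, 3 within numbers 17 to 30, 4 with the neighbouring region covariates and 93 with the first residual component as a covariate. That component is orthogonal to the groups by construction, so it shrinks the errors of choroid plexus genes and leaves their group differences as they were. The Eif5a probe passed in 9 of 15 alternatives, with adjusted p from 0.00149 to 0.768 over all of them. With median scaling Srrt was the 1 probe called. Leaving out single mice gave 0 to 2 probes, and the Eif5a adjusted p ranged from 0.00701 to 0.101. It was lost without responder replicates 1, 3, 4, 5, 9, 14 or 15, or resistant replicates 3, 5, 6, 10, 11, 13, 14 or 15, each leaving 0 probes. There were 2 without resistant replicates 1 or 7 or responder replicates 6, 8, 10, 11 or 13.

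The 951 probes at unadjusted p under 0.05 became 1485 with no filter, which tests 25697 probes, and stayed within 1.5 times in the other alternatives (758 to 1161) and with each mouse left out (775 to 1097). Median scaling gave 924 higher and 229 lower against 535 and 416, a share of 80.1% higher against 56.3%. The 2 lists past the threshold became 0 with an estimated correlation, with fry, with the choroid plexus covariate and within numbers 17 to 30, and 1 with the strict filter, which leaves 32 lists and not choroid plexus. The covariate is built from the choroid plexus markers, so their fall from -0.86 to -0.063 with it is fixed by construction. Oligodendrocyte markers kept their median difference (0.13 against 0.14), and their adjusted p rose to 0.0504 since no list ranked above them. Choroid plexus and oligodendrocyte medians were -0.45 and 0.13 within 17 to 30, and -1.25 and 0.12 within 1 to 16. The lists became 4 with array weights and 5 with median scaling or the first residual component. Leaving out mice gave 1 to 5 lists, with 1 without responder replicates 1, 2, 3 or 6 or resistant replicates 6 or 15, 4 without responder replicates 13 or 15, and 5 without resistant replicate 7.

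Replicate numbers were not treated as pairs, because 8 of 15 same-number pairs, not every pair, had a correlation of deviations over 0.1 (range -0.316 to 0.28). The median was 0.114 against -0.0177 for other pairs across the groups, same-number mice hold adjacent sample numbers, and 4 of 15 resistant arrays correlated best with their own number. An effect shared by same-number mice is therefore not excluded. The replicate block gave 0 probes past the threshold (Eif5a adjusted p = 0.0694) and 1 list. The 20 probes of smallest p, picked on these mice, kept all signs, which is no check. Of other named genes, array weights turned Scn1a to 0.017 and the brightest Eif5a probe to -0.00018. The choroid plexus covariate turned Ttr to 0.68 and the brightest Eif5a probe to -0.0014. Within numbers 1 to 16 Scn8a turned to 0.040. Within numbers 17 to 30 Scn1a turned to 0.16, Ttr to 0.12, the brightest Acot8 probe to -0.035 and the brightest Eif5a probe to -0.069. With single mice left out Scn1a ranged from -0.14 to 0.012, Scn8a from -0.11 to 0.011, Ttr from -0.50 to 0.10 and the brightest Eif5a probe from -0.011 to 0.011. Signal over background limits the efflux pump genes, which were below detection.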

Other observations

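The probes that split the mice into levels, the heat-shock list and the tests on Rbm3, Cirbp, Per2, Mul1 and the choroid plexus were chosen after the data had been seen. So was the count of random splits for probes at unadjusted p under 0.05. Other fixed marker lists of hippocampal cell types did not pass the threshold. At unadjusted p under 0.05 stood 0 of 7 CA1 markers (camera p = 0.494), 0 of 11 CA3 and CA2 markers (camera p = 0.289), 0 of 6 dentate granule markers (camera p = 0.975) and 0 of 15 interneuron markers (camera p = 0.811). The same held for 0 of 15 astrocyte markers (camera p = 0.726) and 0 of 15 microglial markers (camera p = 0.866). Endothelial markers had 2 of 14 lower (camera p = 0.109), among them Emcn at -0.15. Pericyte and smooth muscle markers had 1 higher and 1 lower of 10 (camera p = 0.814). The count was 0 of 13 for meningeal fibroblasts (camera p = 0.276) and 0 of 5 for blood cells (camera p = 0.804). Among markers of tissue next to the hippocampus, it was 0 of 7 for thalamus (camera p = 0.886) and 1 of 9 lower for neocortex (camera p = 0.386). Striatum also had 1 of 9 lower (camera p = 0.748). That gene, Ppp1r1b (DARPP-32), lay at -0.34 (p = 0.0029) and passed when adjusted over the list alone (0.0261), not over all probes (limma adjusted p = 0.397). With the first residual component as a covariate its limma p was 2.73e-07 at the same difference (SE 0.05). It was then among the 93 probes called. That component shrinks the errors of choroid plexus genes, so part of the Ppp1r1b difference may follow those genes.

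The remaining pathway lists did not pass either. Respiratory chain genes had 2 higher and 1 lower of 64 at unadjusted p under 0.05 (camera p = 0.325), and cytosolic ribosomal proteins 1 higher of 41 (camera p = 0.636), Rps6 at 0.13. Oxidative stress genes had 1 higher and 1 lower of 19 (camera p = 0.258). Glucocorticoid-responsive genes had 1 higher and 1 lower of 18 (camera p = 0.227), as did neuropeptides and granins (camera p = 0.949), where Nmb lay at -0.24 (p = 0.00888). Extracellular matrix and perineuronal net genes had 1 of 18 lower (camera p = 0.295).

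Single probes split these outbred mice into levels without regard to the groups. A gap of over 1 log2 unit with at least 3 mice on each side was found for 35 kept probes that did not follow the choroid plexus mean (correlation under 0.5 in size), naming 33 genes, and 2 of them had an unadjusted p under 0.05. The Mff probe had an empty range of 3.37 with 24 mice above it, Abhd16a of 2.98 with 24 above and Cops8 of 2.72 with 20 above, with group differences of -0.22, -0.05 and -0.59 (p = 0.718, 0.933 and 0.319). Both probes with an unadjusted p under 0.05 were for Rusc2, at 0.72 (p = 0.00667) and 0.59 (p = 0.0128), each with 27 mice above its gap. These genes were named after their values were seen.

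Random splits of the 30 mice into 15 and 15 were compared with the real one, 100 splits in all. For the probes past the 5% threshold, 6 splits gave at least the real count of 1, and the highest other count was 4, so chance could not be excluded. For probes at unadjusted p under 0.05, 12 splits gave at least 951, and the highest other count was 1692. For gene lists, 86 splits gave at least the real count of 2, and the highest other was 16, so chance could not be excluded for either. The median of the other splits was 4 lists, which points to a structure shared by the genes of a list across mice.

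Choroid plexus markers lay lower together in resistant mice. A candidate explanation is an amount of attached choroid plexus tissue that differs from mouse to mouse, since the markers rose and fell together within each group, with a median pairwise correlation of 0.93 in resistant and 0.975 in responder mice. Ttr spanned 7.76 to 14.7, 4 of the 12 markers were detected on all 30 arrays, and 92 genes outside the list followed their mean with a correlation over 0.8. That mice with much and little of this tissue fell unevenly into the groups by chance stays open, with a permutation p of 0.181. The same comparison of the groups did not show a difference tied to the drug response and does not exclude one.

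Rbm3 and Cirbp lay lower with Per2 higher in resistant mice. A shift shared by all mice of a part of the sample numbers cancels between the groups, which hold 8 and 8 mice in numbers 1 to 16 and 7 and 7 in 17 to 30. A batch that alternates between odd and even numbers stays open, because the groups alternate in the same way. The mean of Rbm3 and Cirbp differed by -0.43 (95% interval -0.60 to -0.25) and -0.28 (-0.46 to -0.09) in these parts. Per2 on its brightest probe differed by 0.13 (-0.11 to 0.37) and 0.43 (0.28 to 0.59). These values are no independent check, because the genes were picked for their difference over the same mice. A higher brain temperature at dissection may lower both transcripts, but 18 measured heat-shock chaperones did not decide it, with a mean difference of 0.029 (95% interval -0.07 to 0.13), 4 higher and 1 lower, Hspa1a at -0.69, at unadjusted p under 0.05. A shifted hour of dissection was not decided either. Arntl and Clock, taken here as of the phase opposite to Per2, had a mean difference of 0.055 (95% interval -0.04 to 0.15). Most of it came from Clock, at 0.09, with Arntl at 0.02. Within responders Rbm3 and Cirbp correlated with r = 0.72 (permutation p = 0.00269, adjusted over 6 relations 0.0161) and rho = 0.588 (permutation p = 0.0237, adjusted 0.0711), falling to r = 0.414 without 2 mice, and within resistant mice with r = 0.571 (permutation p = 0.026, adjusted 0.0779), rho = 0.634 (permutation p = 0.0132, adjusted 0.0711) and r = 0.667 without 2 mice, while the 4 relations of Per2 with Rbm3 or Cirbp within groups had r from -0.461 to -0.288 (adjusted p from 0.153 to 0.298).

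Mul1 stood at a high level in 11 of 15 resistant and 2 of 15 responder mice. A chromosome segment that differs between mice of the outbred stock is a candidate explanation, since among 17 measured genes within 1 Mb the highest correlation with Mul1 within groups, 0.509 in size, was matched by a share of 0.0403 of 10000 random runs of neighbouring genes. That gene, Nbl1, had r = -0.509 (permutation p = 0.00389, adjusted over the 17 neighbours 0.0661), rho = -0.498 (permutation p = 0.00548) and r = -0.544 without 2 mice. Pink1 is also among these neighbours, with a correlation of 0.42 on its brighter probe, not on the Pink1 probe at -0.22 named above. Nbl1, like Hspa1a, Arntl and Clock, was named after its values were seen. A sequence variant under the probe cannot be told apart from a change in expression, because the array holds 1 probe for Mul1.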
